A study of Rattus norvegicus with 6 samples.

How the data were processed

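The data were a single table of rat genes with a count and an FPKM value for each of 6 BRL-3A libraries, 3 labelled NC and 3 labelled si-hnrnpa2b1. Groups and replicate numbers were taken from the sample titles, and each column was assigned to the sample whose title it carries; 0 columns of per-sample values were left unused. Per the labels' protocols, siRNA was delivered with a lipid reagent for 48 h and total RNA was extracted, purified and treated with DNase before Illumina libraries were made.

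HISAT2 2.0.4, StringTie 1.3.0 and edgeR are named, with the rat build Rnor_6.0, per the submitters' processing notes, which give no role or order for them. The counts deposited by the authors are whole numbers per gene, not normalized, per the file headers and their values, with 1 column per library, so replicates were not pooled. The FPKM values deposited by the authors are linear values: each equals the count divided by a single length per gene and by the column total, to within 0.062%, with no further scaling. Gene models carry Ensembl rat identifiers, symbols and coordinates in the deposited table. The annotation release, the counting program, the treatment of reads that map to several genes and the strand setting are not given in the sources used here. Reads of overlapping or near-identical genes can therefore be assigned to either. Of the 137 genes named by the rule below, 6 are limited by a model that overlaps another holding more than 0.1 times as many counts. Near-identical genes are not part of that number, although some named genes, such as Hnrnpa3 and Elovl6, have another model of the same symbol.

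The table held 30957 genes, of which 14099 had 0 counts in all 6 libraries. Totals per library lay between 13374412 and 15224108. The 10 most abundant genes took 9.41% to 10.2% of each library and mitochondrial genes 6.00% to 6.96%. A count of 0 allows up to 3 counts, which corresponds to 0.197 to 0.224 CPM depending on the library; such limits cover counting error only. Replicates were checked for libraries deposited more than once: over genes with at least 20 counts in a pair, the chi-square per degree of freedom was 2.91 to 6.00, so no pair agreed within sampling noise. The first principal component of log CPM, with 31.3% of the variance, separated the groups.

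Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults (minimum count 10, minimum total count 15), which left 12261 genes, and libraries were scaled by trimmed mean of M-values (TMM), with factors from 0.989 to 1.01. The quasi-likelihood F-test of si-hnrnpa2b1 against NC was two-sided, without covariates, on all 6 libraries, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The common biological coefficient of variation was 0.0638. A filter of at least 2-fold was added for a smaller set. CPM values are TMM-scaled, and fold changes are those of the edgeR fit.

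Before the data were examined, the groups, the tests, the alternatives, the gene lists and a rule for naming genes were fixed. By that rule the text names Hnrnpa2b1, Purb, Pura, Gpam, Cpt1a, Tm7sf2 and Apoa4 in any case. It then names the 10 genes that rose most and the 10 that fell most among those past the threshold that had a gene symbol other than a placeholder, no overlap between groups and a mean of at least 5 CPM in the higher group. Of each gene list it names up to 4 tested members, those with the smallest adjusted p. A few other genes are said to be named after their values were seen.

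The 29 gene lists covered lipogenesis and triglyceride synthesis, cholesterol synthesis, triglyceride hydrolysis and lipid droplets, fatty acid oxidation, lipoproteins and lipid uptake, hnRNP proteins, SR proteins and splicing regulators, m6A machinery, microRNA biogenesis, DNA replication, mitosis, p53 targets, the interferon response, NF-kB targets, ATF4 targets, the unfolded protein response, hypoxia and glycolysis, NRF2 targets, ribosomal proteins, oxidative phosphorylation, histones, extracellular matrix, the insulin-like growth factor axis, early response genes, and markers of hepatocytes, cholangiocytes, stellate cells, endothelial cells and leukocytes. Of their 788 entries, 725 matched a symbol in the table, 19 an older and 1 a current RefSeq symbol, 14 repeated a gene of the same list under another name, and 29 were not matched. The RefSeq table belongs to assembly GRCr8 and was used for names only. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, then with an estimated correlation and with fry, adjusted over the lists. Members past the threshold were counted both over all genes and adjusted over the list alone.

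The genes were tested again with DESeq2 1.42.0, other scalings (relative log expression, upper quartile, total counts alone), no filter on low counts or at least 1 CPM in 3 libraries, limma on log2(FPKM + 1) and log2(FPKM + 0.1) of genes with a mean of at least 1 FPKM in either group, the replicate number as a block, and leaving out each library in turn. On the FPKM scale a fold change understates the change of low genes. Counts of changed members under each setting and list medians after removal of a trend on gene length were added after seeing the data.

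The test was run on simulated counts drawn from the means and library sizes of these samples. Of 50 genes changed by each size, edgeR recovered 46%, 66%, 86% and 100% at log2 changes of 0.3, 0.5, 1 and 2 among 12163 tested genes, and 9 of 169 calls were false. A simulated list of 30 shifted genes had a camera adjusted p of 8.5e-26 and an unchanged one 0.95. The simulated genes were drawn independently, so these values do not test camera on genes that vary together. In the real data the estimated correlation was 0.49 for the interferon list and 0.54 for NF-kB targets, against the preset 0.01. At this depth and with 3 libraries per group, most simulated changes of 2-fold could be seen, and many of 0.3 on the log2 scale could not. No genome was used here, so positions are those of the deposited table and exon structure is not described.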

Results

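RNA sequencing was carried out on 6 libraries of BRL-3A, an established line of cultured rat liver cells; the labels' protocol has siRNAs transfected for 48 h before harvest. The labels put 3 libraries in a group called NC, which is not spelled out and served as the reference (whether these cells received an siRNA is not given in the sources used here), and 3 in a group called si-hnrnpa2b1. Hnrnpa2b1 encodes an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein (hnRNP) family with roles in splicing, transport and stability of transcripts. The series concerns triglyceride metabolism in rat liver and names Purb and hnRNPA2B1 as proteins bound by a long noncoding RNA; that RNA was not analysed here. The comparison addresses which transcripts differ when Hnrnpa2b1 mRNA is lowered.

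The NC libraries held 14058134, 13374412 and 14751764 counts and the si-hnrnpa2b1 libraries 15224108, 14711553 and 14700371 counts. Values are given as CPM (counts scaled to the library total and its TMM factor, the trimmed mean of M-values), mean ± SD over n = 3 libraries per group. Log2 fold changes are si-hnrnpa2b1 over NC with their SE, and the adjusted p named edgeR is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12261 genes. A gene is said to have risen, fallen or changed where that adjusted p was below 0.05. In every gene named here as changed, the 3 values of one group lay entirely above those of the other. The labels do not say that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

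Hnrnpa2b1 itself (ENSRNOG00000011175, chromosome 4, positions 81237496 to 81241282 of Rnor_6.0) was lowered but still abundant after siRNA. The NC libraries gave 953, 1064 and 1025 CPM (1014 ± 56.0) and the si-hnrnpa2b1 libraries 662, 584 and 573 CPM (607 ± 48.2). The mRNA fell by 40.2%, a log2 fold change of -0.74 ± 0.06 (edgeR adjusted p = 2.3e-06). Of 12261 tested genes 650 (5.30%) changed, Hnrnpa2b1 included: 289 rose and 361 fell. Most changes were small: the median size among the 650 genes was 0.33 on the log2 scale, or 1.26-fold, and 39 genes changed at least 2-fold, 20 upward and 19 downward. Yet 71 of the changed genes moved by more than Hnrnpa2b1 did. The groups did not overlap in 2868 genes (23.4%), where chance gives 10%. The number of changed genes was 390, 380 and 379 without si-hnrnpa2b1 replicate 1, 2 or 3. The number changed at least 2-fold was 24 without si-hnrnpa2b1 replicate 2 and 6 by limma on log2(FPKM + 1).

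**Figure D1:**
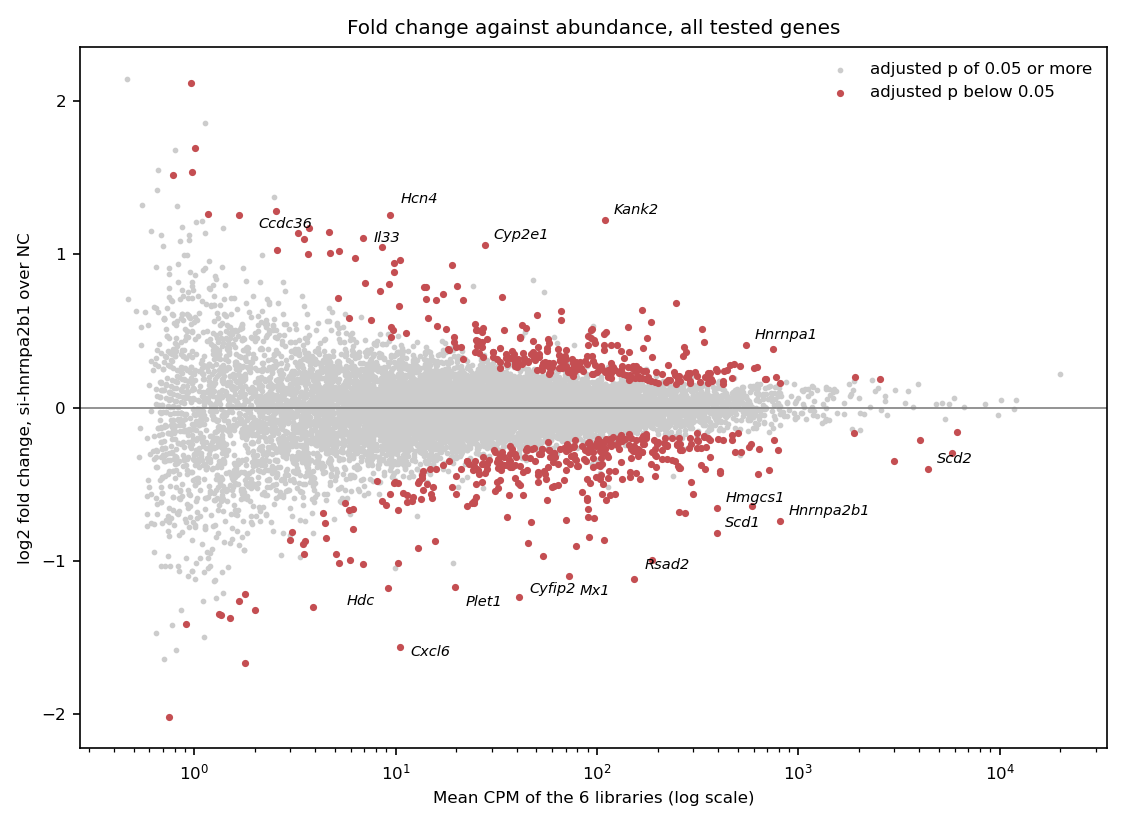
Log2 fold change of si-hnrnpa2b1 over NC (vertical axis) against the mean CPM of the 6 libraries (horizontal axis, log scale) for the 12261 tested genes, 1 point per gene. Red points are the 650 genes with an edgeR adjusted p below 0.05, and names mark Hnrnpa2b1 at -0.74, some of the largest rises and falls, and a few lipid genes.

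The largest rise among well-expressed genes was that of Hcn4, a pacemaker ion channel, which went from 5.56 ± 0.140 to 13.3 ± 2.55 CPM (log2 1.26 ± 0.16, edgeR adjusted p = 1.6e-04). Kank2, a talin-binding protein of cell adhesions encoded on chromosome 8 (22791995 to 22821397), rose from 65.7 ± 4.43 to 154 ± 4.83 CPM (log2 1.22 ± 0.06) and had the smallest edgeR adjusted p of all genes, 1.2e-08. The alarmin cytokine Il33 rose from 4.39 to 9.44 CPM, the Wnt inhibitor Wif1 from 3.46 to 7.02 CPM, the matrix metalloproteinase Mmp10 from 5.62 to 11.6 CPM, and the ErbB ligand Nrg1 from 7.10 to 13.9 CPM. Ccdc36, a meiotic protein, the ethanol-oxidising cytochrome Cyp2e1 and the cyclooxygenase Ptgs1 completed the group with log2 fold changes of 1.15, 1.06 and 0.97. Carbonic anhydrase Car2 rose by 1.01 on the log2 scale (edgeR adjusted p = 0.018), a call that was lost without NC replicate 2, si-hnrnpa2b1 replicate 2 or si-hnrnpa2b1 replicate 3 and by limma on FPKM, with adjusted p up to 0.10.

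The largest fall among these genes was that of the neutrophil chemokine Cxcl6 (chromosome 14, 18860264 to 18862407), from 15.8 ± 2.24 to 5.34 ± 0.506 CPM (log2 -1.56 ± 0.14, edgeR adjusted p = 8.8e-06). Hdc, which makes histamine from histidine, fell from 12.8 ± 1.37 to 5.65 ± 1.69 CPM, and Myo1f, an unconventional myosin, from 13.9 ± 0.266 to 6.84 ± 0.827 CPM. C1qtnf7 and Phyhipl fell by 1.02 and 0.99 on the log2 scale. The interferon-induced genes Rsad2, Mx1 and Cxcl10 were also among the 10 largest falls. Cyfip2, a subunit of the WAVE complex that controls actin, went from 57.5 ± 24.2 to 24.4 ± 0.774 CPM, with NC values of 67.6, 75.1 and 29.95 CPM. Plet1, a surface protein of epithelial progenitors, went from 27.4 ± 13.4 to 12.1 ± 0.567 CPM, with NC values of 20.9, 42.8 and 18.5 CPM; its log2 fold change was -1.17, and -0.70 without NC replicate 2. Both passed edgeR's test with Benjamini-Hochberg adjustment (adjusted p = 0.0036 and 0.0068) and missed it by limma on log2(FPKM + 1), with adjusted p up to 0.089 and 0.068.

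Of 29 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 12, 8 upward and 4 downward. With an estimated correlation between genes, camera called 0 of the 28 lists it could test, and 6 had an unadjusted p below 0.05. fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, called 10 lists, of which 7 were among camera's 12. Of those 12 it did not call NF-kB targets, DNA replication, p53 targets, ribosomal proteins and early response genes (fry adjusted p = 0.11, 0.070, 0.070, 0.088 and 0.14). It called 3 lists that camera did not: fatty acid oxidation downward (0.028), NRF2 targets upward (0.042) and cholangiocyte markers downward (0.042).

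Some genes of fatty acid synthesis fell after si-hnrnpa2b1, while the genes singled out by the study's theme of triglyceride metabolism did not pass the test. Scd1, the stearoyl-CoA desaturase (ENSRNOG00000013552, chromosome 1, 264160129 to 264172729), fell from 504 ± 16.2 to 285 ± 1.64 CPM (log2 -0.82 ± 0.04, edgeR adjusted p = 1.7e-08). Its paralog Scd2 fell from 5024 ± 139 to 3807 ± 64.8 CPM (log2 -0.40 ± 0.04) and the fatty acid elongase Elovl6 from 32.3 ± 1.31 to 24.5 ± 0.665 CPM (log2 -0.40 ± 0.08). A second gene model named Elovl6 gave -0.21 ± 0.16 (edgeR adjusted p = 0.51). Of the 28 tested genes of lipogenesis and triglyceride synthesis, 0 rose, 5 fell and 23 did not pass; adjusted over the list alone, 0 rose and 9 fell. The remaining falls were those of Acly, which supplies cytosolic acetyl-CoA (380 ± 20.7 to 331 ± 5.95 CPM, edgeR adjusted p = 0.020), and of the phosphatidate phosphatase Lpin1, named here after its values were seen (13.6 ± 2.23 to 9.16 ± 0.891 CPM, edgeR adjusted p = 0.024). Both calls were lost by limma on FPKM. The Acly call was also lost without any single library other than NC replicate 2, the Lpin1 call without NC replicate 1, si-hnrnpa2b1 replicate 1 or si-hnrnpa2b1 replicate 2, and the list's count was 3 without NC replicate 1, si-hnrnpa2b1 replicate 1 or si-hnrnpa2b1 replicate 2. The list median was -0.11 (camera adjusted p = 1.5e-04; adjusted p = 0.23 with an estimated correlation).

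**Figure D2:**
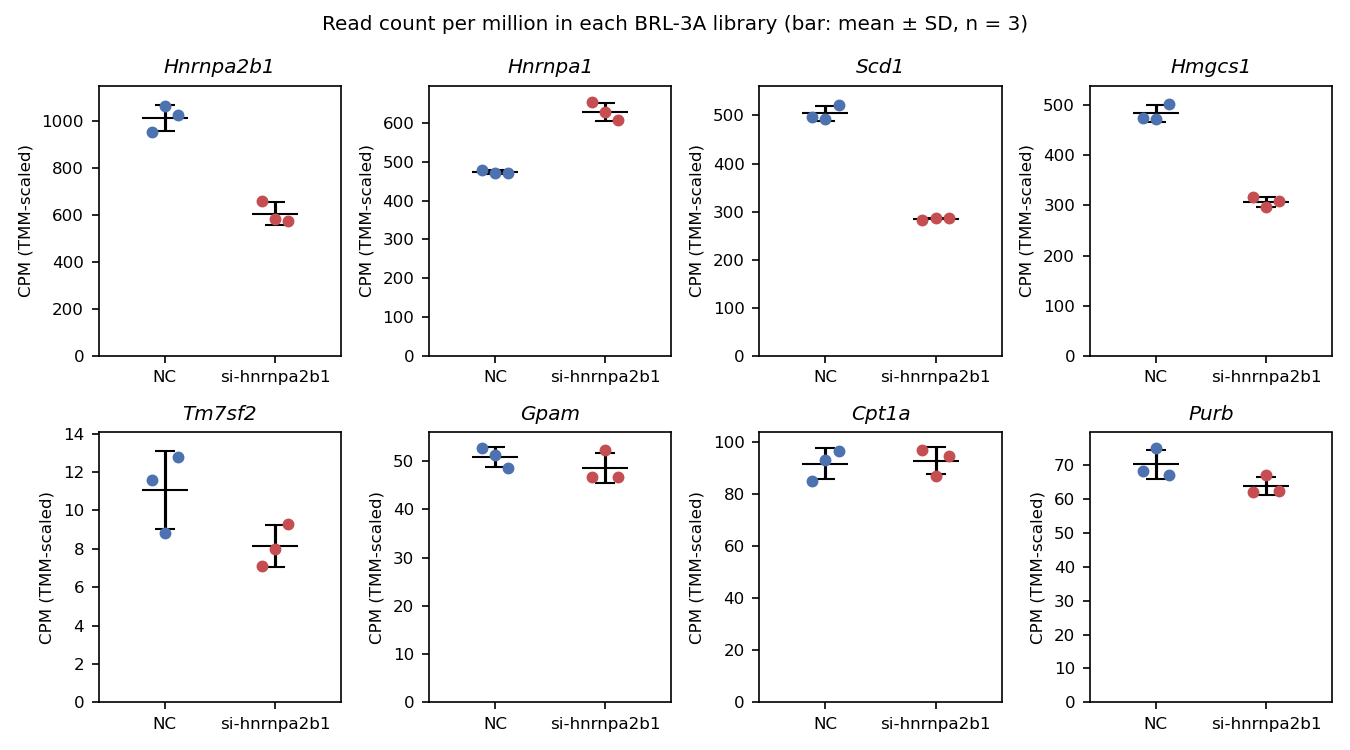
CPM scaled by trimmed mean of M-values (vertical axes, each starting at 0) in the 3 NC and the 3 si-hnrnpa2b1 libraries for 8 genes, 1 point per library, with the mean and SD of each group. Hnrnpa2b1, Scd1 and Hmgcs1 lay lower and Hnrnpa1 higher in the 3 si-hnrnpa2b1 libraries than in any NC library, and edgeR's test was not passed by Tm7sf2, Gpam, Cpt1a and Purb, whose groups overlapped in all but Purb.

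Gpam, the mitochondrial acyltransferase that opens glycerolipid synthesis (chromosome 1, 275846819 to 275906686), had 50.9 ± 2.02 CPM in NC and 48.6 ± 3.16 CPM in si-hnrnpa2b1 libraries (log2 -0.07 ± 0.07, edgeR adjusted p = 0.68). Cpt1a, which admits fatty acids to mitochondrial oxidation (chromosome 1, 218569510 to 218629678), had 91.5 ± 5.84 and 92.6 ± 5.24 CPM (log2 0.02 ± 0.06, edgeR adjusted p = 0.93); the sign turned without NC replicate 1 (-0.03) and without si-hnrnpa2b1 replicate 1 (-0.01). Tm7sf2, a sterol reductase of cholesterol synthesis (chromosome 1, 221425987 to 221431713), had 11.1 ± 2.02 and 8.13 ± 1.10 CPM (log2 -0.45 ± 0.15, edgeR adjusted p = 0.12). It passed without NC replicate 2 (log2 -0.58, edgeR adjusted p = 0.033), with adjusted p from 0.033 to 0.35 over all alternatives. Its model overlaps that of Vps51, which held 2322 counts against 833 for Tm7sf2. The apolipoprotein gene Apoa4 (chromosome 8, 50537009 to 50539376) had 0 counts in all 6 libraries; with 3 counts as the limit, that allows up to 0.197 to 0.224 CPM per library. Purb, a DNA- and RNA-binding protein (chromosome 14, 86736878 to 86739335), had 70.1 ± 4.27 and 63.7 ± 2.71 CPM (log2 -0.14 ± 0.06, edgeR adjusted p = 0.27). Its relative Pura had 22.5 ± 2.17 and 23.8 ± 1.39 CPM (log2 0.09 ± 0.10, edgeR adjusted p = 0.71).

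Most tested genes of cholesterol synthesis fell. Hmgcs1, which makes the precursor of mevalonate (ENSRNOG00000016552, chromosome 2, 52431601 to 52445055), fell from 483 ± 16.3 to 307 ± 10.4 CPM (log2 -0.65 ± 0.04, edgeR adjusted p = 5.5e-07). The squalene epoxidase Sqle fell from 222 ± 4.67 to 170 ± 0.465 CPM, the isopentenyl isomerase Idi1 from 155 ± 9.10 to 113 ± 3.44 CPM, and the sterol-regulated anchor protein Insig1 from 180 ± 12.6 to 134 ± 4.32 CPM. Of the 26 tested genes of cholesterol synthesis and other SREBP2 targets, 0 rose, 17 fell and 9 did not pass; adjusted over the list alone, 0 rose and 22 fell. At the median these genes moved by -0.38, a fall of 23.2% (camera adjusted p = 4.2e-23; adjusted p = 0.17 with an estimated correlation). The model of Idi1 overlaps that of Wdr37, which held 1730 counts against 11600 for Idi1.

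Most tested interferon-stimulated genes fell. Rsad2, the antiviral enzyme viperin (chromosome 6, 45655954 to 45669148), had 216, 243 and 169 CPM in the NC and 97.8, 89.2 and 102 CPM in the si-hnrnpa2b1 libraries (log2 -1.12 ± 0.10, edgeR adjusted p = 7.1e-06). The chemokine Cxcl10 fell from 249 ± 40.3 to 125 ± 7.91 CPM, the antiviral GTPase Mx1 from 99.4 ± 32.3 to 46.2 ± 2.96 CPM, the double-stranded RNA sensor Ifih1 from 134 ± 10.5 to 88.2 ± 1.39 CPM, and the interferon signalling factor Stat2 from 343 ± 15.7 to 245 ± 12.5 CPM. Of the 30 tested genes of the interferon and double-stranded RNA response, 0 rose, 23 fell and 7 did not pass; adjusted over the list alone, 0 rose and 25 fell. Their median was -0.46 (camera adjusted p = 9.9e-28; adjusted p = 0.21 with an estimated correlation). The spread between NC libraries was wider than between si-hnrnpa2b1 libraries: the mean log2 CPM of the list was 6.60, 6.78 and 6.41 in NC and 6.11, 6.05 and 6.20 in si-hnrnpa2b1 libraries.

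Some targets of NF-kB fell. The neutrophil chemokine Cxcl1 fell from 811 ± 40.3 to 612 ± 16.7 CPM (log2 -0.41 ± 0.05, edgeR adjusted p = 7.5e-05), the mitochondrial superoxide dismutase Sod2 from 468 ± 30.7 to 351 ± 7.05 CPM, complement C3 from 3358 ± 22.1 to 2634 ± 117 CPM, and Nfkb1, a subunit of the factor itself, from 248 ± 7.51 to 197 ± 8.39 CPM. Of the 26 tested genes of this list, 0 rose, 7 fell and 19 did not pass; adjusted over the list alone, 2 rose and 10 fell. A median of -0.23 was found (camera adjusted p = 4.7e-06; adjusted p = 0.41 with an estimated correlation).

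Most tested genes of the integrated stress response rose. Stc2, a secreted stanniocalcin (chromosome 10, 16542882 to 16553295), rose from 13.1 ± 0.864 to 25.1 ± 2.25 CPM (log2 0.93 ± 0.10, edgeR adjusted p = 6.6e-05). Mthfd2 of mitochondrial folate metabolism rose from 39.7 ± 0.628 to 60.5 ± 4.14 CPM, the amino acid transporter subunit Slc3a2 from 243 ± 3.29 to 312 ± 7.51 CPM, and the stress transcription factor Ddit3 from 25.6 ± 3.73 to 42.1 ± 2.41 CPM. The Ddit3 model overlaps that of Mars, which held 7761 counts against 2951. Of the 27 tested ATF4 targets, 21 rose, 0 fell and 6 did not pass; adjusted over the list alone, 23 rose and 1 fell. Over this list the median was 0.26 (camera adjusted p = 2.8e-21; adjusted p = 0.16 with an estimated correlation). The count of changed members was 13, 12 and 13 without si-hnrnpa2b1 replicate 1, 2 or 3, and 12 by limma on log2(FPKM + 1).

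Some chaperones of the endoplasmic reticulum rose. Creld2 rose from 53.2 ± 2.15 to 79.0 ± 3.57 CPM (log2 0.57 ± 0.06, edgeR adjusted p = 5.8e-05), the co-chaperone Dnajb9 from 36.7 ± 1.45 to 52.6 ± 3.53 CPM, and Herpud1, which acts in disposal of misfolded proteins, from 77.6 ± 4.91 to 110 ± 15.1 CPM. Hyou1, a chaperone induced by low oxygen, rose by 0.19 ± 0.04 on the log2 scale (edgeR adjusted p = 0.013), a call lost without si-hnrnpa2b1 replicate 3 (adjusted p = 0.085). Of 25 tested members of the unfolded protein response list, 9 rose, 0 fell and 16 did not pass; adjusted over the list alone, 12 rose and 1 fell. The list median was 0.11 (camera adjusted p = 9.3e-10; adjusted p = 0.16 with an estimated correlation). Without si-hnrnpa2b1 replicate 3, 3 members passed.

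**Figure D3:**
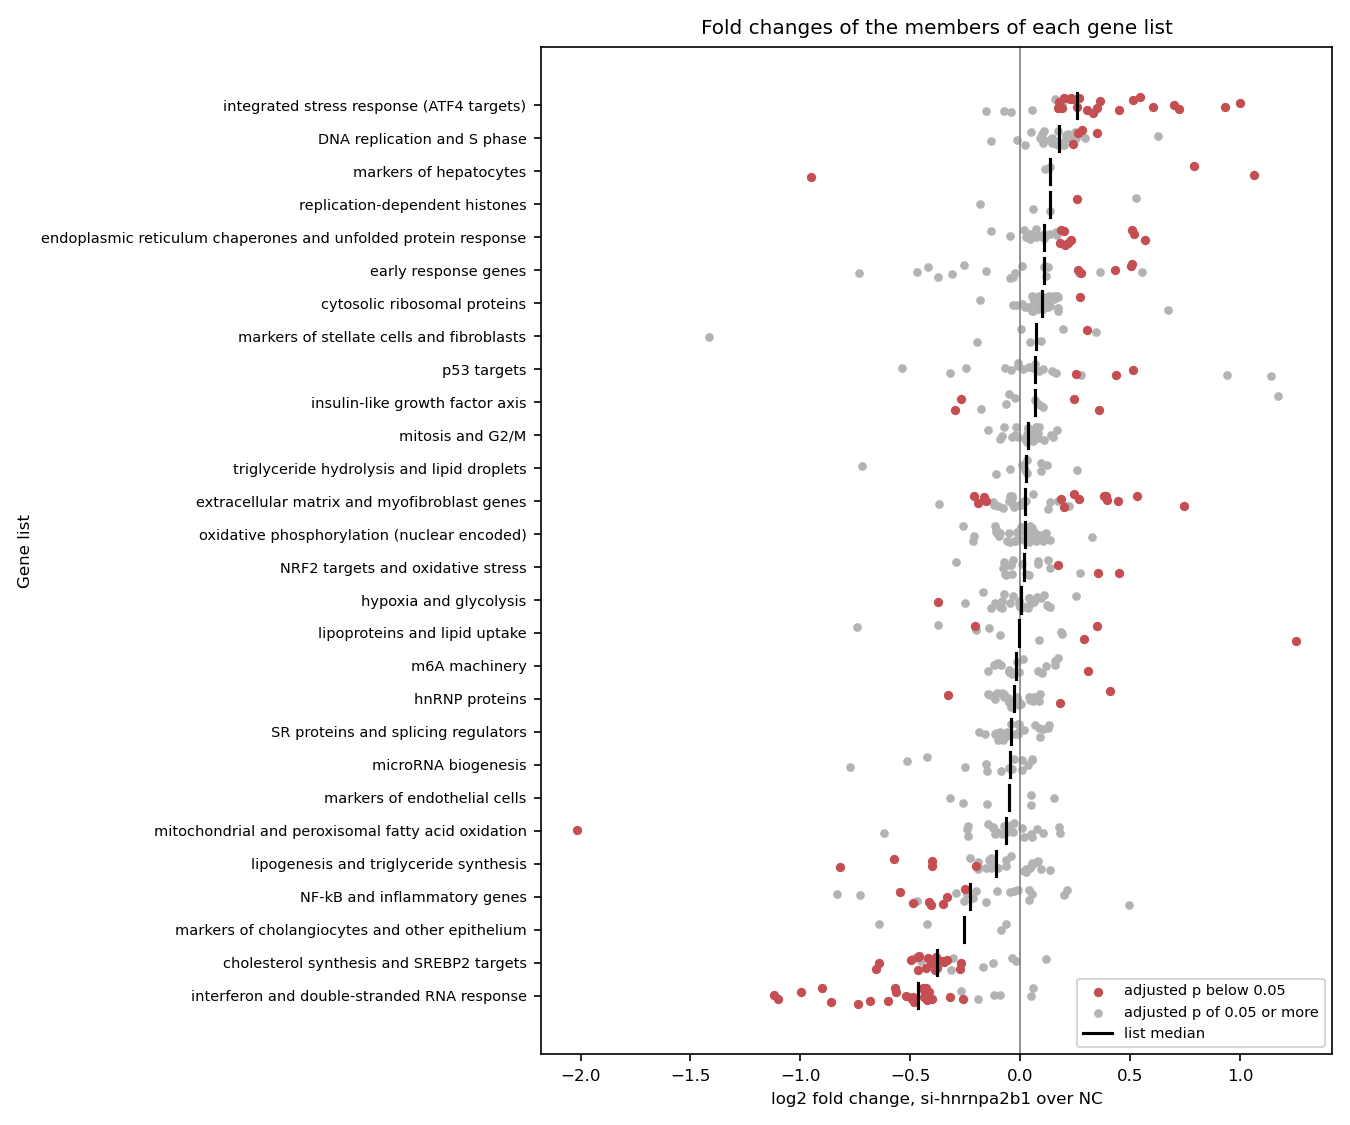
Log2 fold changes of si-hnrnpa2b1 over NC (horizontal axis) of the tested members of 28 gene lists (vertical axis, ordered by median), 1 point per gene, red where the edgeR adjusted p was below 0.05, with a bar at each list median. The medians lie between -0.46 for the interferon list and 0.26 for the ATF4 targets, and the red points of those lists and of the cholesterol list lie on 1 side of 0.

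Among relatives of the targeted gene, Hnrnpa1, a close paralog that also binds RNA in splicing, rose from 474 ± 5.15 to 629 ± 23.3 CPM (log2 0.41 ± 0.04, edgeR adjusted p = 3.7e-05). Hnrnpa3 went from 217 ± 6.13 to 247 ± 10.97 CPM (log2 0.18 ± 0.05, edgeR adjusted p = 0.032), a call lost without NC replicate 1, NC replicate 2, si-hnrnpa2b1 replicate 1 or si-hnrnpa2b1 replicate 2, by limma on FPKM and with the replicate block, with adjusted p up to 0.13. Ptbp3, a polypyrimidine tract binding protein, fell from 117 ± 6.53 to 93.1 ± 8.42 CPM (log2 -0.33 ± 0.07, edgeR adjusted p = 0.0081); limma on log2(FPKM + 1) did not call it, with adjusted p up to 0.058. Of 26 tested hnRNP genes other than Hnrnpa2b1, 2 rose, 1 fell and 23 did not pass, as when adjusted over the list alone, and camera did not call the list (median -0.03, adjusted p = 0.84). How reads shared by paralogs were counted is not given in the sources used here, so the levels of these related genes are uncertain.

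Other RNA-processing groups held few changed genes. Among 25 SR proteins and splicing regulators 0 passed by edgeR or by DESeq2, 4 having an unadjusted p below 0.05; without NC replicate 2, 1 passed. Among 16 genes of microRNA biogenesis 0 passed by either tool, with 3 below 0.05 unadjusted; without NC replicate 1 or si-hnrnpa2b1 replicate 1, 1 passed. Of 20 genes of the m6A machinery, which writes, reads and erases adenosine methylation in RNA, the writer subunit Rbm15b rose from 44.1 ± 2.27 to 54.6 ± 0.491 CPM (log2 0.31 ± 0.06, edgeR adjusted p = 0.010); without NC replicate 1 its adjusted p was 0.054. Adjusted over the list alone, these lists gave 0, 0 and 1 changed genes, and camera called none of them (adjusted p = 0.28, 0.14 and 0.82). The m6A median of -0.02 was opposite in sign to its mean and to camera's direction.

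Some genes of DNA replication rose. The replication licensing factor Cdc6 rose from 31.1 ± 0.640 to 39.7 ± 0.610 CPM (log2 0.35 ± 0.07, edgeR adjusted p = 0.0068). Mcm4, Chaf1b and Uhrf1 rose by 0.24, 0.26 and 0.28 on the log2 scale. Of 32 tested genes of this list 4 rose, 0 fell and 28 did not pass; adjusted over the list alone, 15 rose and 0 fell. Without si-hnrnpa2b1 replicate 1, 2 or 3 only 1 passed, and without NC replicate 2 there were 2; Chaf1b and Uhrf1 were lost without NC replicate 1 and with the replicate block too, Chaf1b by DESeq2, and Mcm4 and Uhrf1 by limma on FPKM. Their median was 0.18, with 30 of 32 fold changes above 0 (camera adjusted p = 5.3e-10; adjusted p = 0.36 with an estimated correlation). Of 31 genes of mitosis and G2/M 0 passed by edgeR or by DESeq2, nor adjusted over the list alone, and 4 had an unadjusted p below 0.05; camera gave an adjusted p of 0.18 for a median of 0.04, and 0.039 upward without si-hnrnpa2b1 replicate 3. Cytosolic ribosomal protein genes had a median of 0.10 over 44 genes (camera adjusted p = 3.0e-07; adjusted p = 0.36 with an estimated correlation), although 1 gene rose, 0 fell and 43 did not pass, also adjusted over the list alone. That gene was a model named Rpl37, which overlaps Vps53 and did not pass without NC replicate 1 or any single si-hnrnpa2b1 library; without NC replicate 3, 3 genes passed.

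Among p53 targets, the growth arrest gene Gadd45a rose from 40.8 ± 0.434 to 55.2 ± 3.06 CPM (log2 0.44 ± 0.07, edgeR adjusted p = 9.2e-04) and Sesn2, which is also on the ATF4 list, from 78.3 ± 8.09 to 112 ± 10.8 CPM. With Phlda3, 3 of 21 tested genes rose, 0 fell and 18 did not pass, also adjusted over the list alone. The Phlda3 call was lost without NC replicate 3, si-hnrnpa2b1 replicate 1 or si-hnrnpa2b1 replicate 3. The list median was 0.07 (camera adjusted p = 0.018; adjusted p = 0.40 with an estimated correlation), and camera's call was lost without NC replicate 3 (0.066) or si-hnrnpa2b1 replicate 2 (0.17).

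Early response genes gave 5 rises and 0 falls among 23 tested genes, 18 not passing; adjusted over the list alone, 5 rose and 1 fell. Myc, a growth-promoting transcription factor, rose from 28.7 ± 1.61 to 40.7 ± 0.696 CPM (log2 0.50 ± 0.07, edgeR adjusted p = 6.4e-04) and Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, from 20.8 ± 1.74 to 29.6 ± 1.96 CPM. Klf4, Spry2 and, named after its values were seen, the phosphatase gene Dusp1 rose by 0.26, 0.43 and 0.28 on the log2 scale. Without NC replicate 1, NC replicate 3 or si-hnrnpa2b1 replicate 1 the count was 3 and Spry2 lost its call; Klf4 lost its call without si-hnrnpa2b1 replicate 3, and Dusp1 without any single library other than NC replicate 2, by DESeq2, by limma on FPKM and with the replicate block. The list median was 0.11 (camera adjusted p = 0.019; adjusted p = 0.42 with an estimated correlation), and camera's call was lost without NC replicate 1 (0.062) or NC replicate 3 (0.15).

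Genes of the extracellular matrix went both ways. Thbs2, a matricellular thrombospondin, rose from 652 ± 4.16 to 850 ± 27.8 CPM (log2 0.38 ± 0.04, edgeR adjusted p = 5.8e-05), the integrin ligand Cyr61 from 147 ± 5.11 to 192 ± 2.73 CPM, the collagen crosslinker Loxl2 from 233 ± 9.44 to 306 ± 24.7 CPM, and the smooth muscle protein Tagln from 82.0 ± 7.59 to 112 ± 5.21 CPM. The Tagln model overlaps that of Sidt2, which held 7446 counts against 8452. Of 36 tested genes 10 rose, 4 fell and 22 did not pass; adjusted over the list alone, 13 rose and 4 fell. Across both directions the median was 0.02 (camera adjusted p = 0.0097; adjusted p = 0.24 with an estimated correlation). Without si-hnrnpa2b1 replicate 2, 5 rose and 1 fell, and 7 rose and 1 or 2 fell without NC replicate 1, NC replicate 3 or si-hnrnpa2b1 replicate 3.

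In the insulin-like growth factor axis, the binding protein Igfbp4 rose from 126 ± 5.17 to 161 ± 6.66 CPM (log2 0.36 ± 0.05, edgeR adjusted p = 5.7e-04). The growth factor Igf2, 1 of the 10 most abundant transcripts of these cells, fell from 6428 ± 453 to 5237 ± 302 CPM (log2 -0.30 ± 0.06, edgeR adjusted p = 0.0057). With Irs1 higher and Igfbp5 lower, 2 of 13 tested genes rose, 2 fell and 9 did not pass; adjusted over the list alone, 3 rose and 2 fell. Camera, which looks for a shift in 1 direction, did not call the list (median 0.07, adjusted p = 0.73). A separate fry test for changes in either direction gave an adjusted p of 1.7e-07. That test compares a list with no other genes and called most lists, hnRNP genes (2.7e-04) and lipoprotein and lipid uptake genes (7.3e-04) included. Without si-hnrnpa2b1 replicate 2 or si-hnrnpa2b1 replicate 3, 1 rose and 1 fell. The calls of Irs1 (edgeR adjusted p = 0.047) and Igfbp5 (edgeR adjusted p = 0.021) were lost in those fits, and without NC replicate 3; The log2 fold change of Irs1 was 0.25, and 0.16 without si-hnrnpa2b1 replicate 2. Irs1 was also lost without NC replicate 1, with total counts alone and with the replicate block, Igfbp5 without si-hnrnpa2b1 replicate 1, and both by limma on FPKM.

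Camera called none of the other lipid lists. Among 12 tested genes of triglyceride hydrolysis and lipid droplets 0 passed by edgeR or DESeq2, and 0 had an unadjusted p below 0.05 (median 0.03, mean -0.02, camera adjusted p = 0.85). Of 24 genes of fatty acid oxidation, the peroxisomal enzyme Ehhadh fell from 1.20 ± 0.254 to 0.292 ± 0.105 CPM (edgeR adjusted p = 0.014), close to the 0.197 to 0.224 CPM that 3 counts represent, and lost its call without NC replicate 1, si-hnrnpa2b1 replicate 1 or si-hnrnpa2b1 replicate 2. The other 23 did not pass (median -0.07, camera adjusted p = 0.16, fry adjusted p = 0.028 downward); without NC replicate 2, 2 passed. Of 12 lipoprotein and lipid uptake genes 3 rose, 1 fell and 8 did not pass, with a median of -0.0034, a mean of 0.05 and a camera adjusted p of 0.85. These were the lipoprotein receptor Vldlr (log2 0.35, also on the ATF4 list), the fatty acid binding proteins Fabp4 (1.26) and Fabp5 (0.29), and the cholesterol exporter Abca1 (-0.21). Their edgeR adjusted p ran from 0.012 to 0.031. Whichever library was left out, 1 or 2 genes passed: Vldlr was lost without si-hnrnpa2b1 replicate 2, Fabp4 without replicate 1 or 2 of either group, Fabp5 without NC replicate 2 or 3 or si-hnrnpa2b1 replicate 1 or 3, and Abca1 without any library but NC replicate 2. Limma on FPKM did not call Vldlr, Fabp5 or Abca1, and the replicate block did not call Fabp4 or Abca1. Adjusted over the list alone, the 3 lists gave 0, 1 and 5 changed genes.

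In the remaining metabolic and stress lists, the collagen prolyl hydroxylase P4ha2 fell from 372 ± 20.1 to 287 ± 3.48 CPM (log2 -0.37 ± 0.05, edgeR adjusted p = 1.7e-04) as the sole changed gene among 30 of hypoxia and glycolysis; DESeq2 called 3 genes, and 2 passed without NC replicate 2 or NC replicate 3. Of 20 NRF2 targets, 3 rose and 0 fell, with 1 left without si-hnrnpa2b1 replicate 2. They were the cystine transporter Slc7a11 (log2 0.45, also on the ATF4 list), thioredoxin Txn1 (0.35) and its reductase Txnrd1 (0.17). Txnrd1 was also lost without any other single library except NC replicate 2 and with the replicate block, and limma on FPKM called neither it nor Slc7a11. Of 40 nuclear genes of oxidative phosphorylation 0 passed by edgeR or DESeq2, with 3 at an unadjusted p below 0.05 and 1 passing by limma on log2(FPKM + 1) or without NC replicate 2. Of 5 tested replication-dependent histone genes, Hist1h1c rose by 0.26 on the log2 scale (edgeR adjusted p = 0.030), a call lost with the replicate block and without NC replicate 1 or any single si-hnrnpa2b1 library. Camera called none of these lists (adjusted p = 0.85, 0.23, 0.82 and 0.21) and fry called the NRF2 targets upward (0.042), the hypoxia median being above 0 and its mean and camera's direction below, and adjusted over the list alone they gave 1, 3, 0 and 1 changed genes.

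Few markers of hepatocytes, cholangiocytes and leukocytes passed the filter on low counts. Of stellate and fibroblast markers 8 of 13 passed it, and of endothelial markers 6 of 10. The matrix genes Fn1, Col1a1, Sparc and Lox were among the 10 most abundant genes. Of the 25 hepatocyte markers 5 were tested: Cyp2e1 rose (log2 1.06), the haem carrier Hpx rose from 14.8 ± 2.10 to 25.6 ± 0.840 CPM (log2 0.79 ± 0.11, edgeR adjusted p = 4.4e-04), and haptoglobin, Hp, fell from 6.65 ± 0.394 to 3.43 ± 0.448 CPM (log2 -0.95 ± 0.17, edgeR adjusted p = 0.0039). The other 2, G6pc among them, did not pass, and adjusted over the list alone, 3 rose and 1 fell. The G6pc model used held 17207 counts and a second model of that symbol 8, so its identity is uncertain. Camera's adjusted p was 0.017 for a median of 0.14 (adjusted p = 0.23 with an estimated correlation), and its call was lost without NC replicate 3 or any single si-hnrnpa2b1 library, with adjusted p up to 0.11 in those fits, and without the filter on low counts. The stellate cell filament gene Des rose from 58.4 ± 3.18 to 72.2 ± 4.63 CPM (edgeR adjusted p = 0.014), lost without NC replicate 1 or si-hnrnpa2b1 replicate 1, as the sole changed gene of 8 stellate and fibroblast markers. Among 4 cholangiocyte, 6 endothelial and 1 leukocyte markers tested, 0 passed by edgeR or DESeq2, with 1, 1 and 0 at an unadjusted p below 0.05. Adjusted over the list alone, the stellate list gave 1 changed gene and the last 3 gave 0. Camera did not call the stellate, cholangiocyte or endothelial lists (adjusted p = 0.40, 0.32 and 0.87; fry called the cholangiocyte list downward, 0.042) and was not run on the single leukocyte gene. The stellate median of 0.07 and mean of -0.08 differed in sign.

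Further list members named by the rule did not pass edgeR's test, and their log2 fold changes were as follows. Among lipid genes these were Plin3 -0.11, Pnpla3 -0.72, Mgll 0.12 and Lipe 0.26 for triglyceride hydrolysis, and Acadvl -0.24, Cpt1b -0.62 and Etfa 0.18 for fatty acid oxidation. The model of Cpt1b overlaps that of Chkb, which held 1905 counts against 341. In RNA processing they were Hnrnpm -0.11 for hnRNP genes, Mbnl3 -0.19, Mbnl1 -0.16, Srrm1 0.13 and Mbnl2 -0.11 for splicing regulators, Mettl14 0.16, RGD1559904 -0.11 and Igf2bp3 -0.14 for the m6A machinery, and Tnrc6b -0.52, Ago3 -0.42, Ago4 -0.77 and Ago2 -0.15 for microRNA biogenesis. Growth and stress lists gave Kif23 0.17, Aurkb 0.15, Ccnb1 -0.15 and Plk1 0.11 for mitosis, Mdm2 0.16 for p53 targets, Ndrg1 -0.25, Egln3 -0.17 and P4ha1 0.12 for hypoxia, and Hmox1 0.14 for NRF2 targets. For ribosomal proteins the values were Rpl35 0.15 and Rps24 0.15, for oxidative phosphorylation Ndufa6 0.33, Sdhd -0.21 and Atp5c1 0.12, and for histones Hist2h2aa2 0.53, Hist1h4b 0.13 and Hist1h2bb -0.18. Cell type markers gave G6pc 0.11 for hepatocytes, Krt7 -0.42, Sox9 -0.64, Krt8 -0.06 and Spp1 -0.08 for cholangiocytes, Pdgfra -1.42, Hand2 0.19 and Dcn 0.10 for stellate cells, Eng -0.15, Tek 0.15, Lyve1 -0.26 and Stab2 -0.32 for endothelial cells, and Cd68 0.20 for leukocytes. Some passed elsewhere: Acadvl, Srrm1 and Sdhd without NC replicate 2, Ndrg1 without NC replicate 3, Tnrc6b without NC replicate 1 or si-hnrnpa2b1 replicate 1, Rpl35 by DESeq2 or without NC replicate 3, P4ha1 by DESeq2, and Ndufa6 by limma on log2(FPKM + 1). The sign turned for Hist1h2bb without NC replicate 1 or si-hnrnpa2b1 replicate 1, for Lyve1 without si-hnrnpa2b1 replicate 3 and for Cd68 without si-hnrnpa2b1 replicate 1. Sizes moved too when 1 library was left out. Lipe ranged from 0.0039 to 0.45, Pnpla3 from -1.04 to -0.37, Mgll from 0.073 to 0.16 and Plin3 from -0.14 to -0.070. Sox9 ranged from -1.10 to -0.32, Krt7 from -0.54 to -0.21 and Pdgfra from -2.05 to -0.90. For Spp1 the range was -0.14 to -0.0091 and for Dcn 0.029 to 0.15.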

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

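The counts of changed list members under each setting were chosen only after the result was seen; the other alternatives were planned. The fall of Hnrnpa2b1 kept its direction and its side of the threshold under all 15 alternatives, with log2 fold changes from -0.81 to -0.70, as did Purb, Pura and Gpam, which never passed. Of 130 other genes named by the rule, 79 were called, 53 of these had the same verdict under every alternative and 0 reversed. Over all of these genes and alternatives, 1788 values had the same verdict, 115 lost the call, 10 gained one and 4 reversed. The reversals were of uncalled genes: Hist1h2bb was 0.052 without NC replicate 1 and 0.059 without si-hnrnpa2b1 replicate 1 (range -0.37 to 0.059 without 1 library), Lyve1 was 0.021 without si-hnrnpa2b1 replicate 3 (range -0.58 to 0.021), and Cd68 was -0.12 without si-hnrnpa2b1 replicate 1 (range -0.12 to 0.39). Cpt1a was -0.032 without NC replicate 1 and -0.013 without si-hnrnpa2b1 replicate 1, with a range of -0.032 to 0.065 over the fits without 1 library. The cause was not tested. Tm7sf2 ranged from -0.58 to -0.33 over the same fits and passed without NC replicate 2 (-0.58, edgeR adjusted p = 0.033, range 0.033 to 0.35).

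The number of changed genes was 650 in the fit reported. It was 633 by DESeq2, 635 to 653 with other scalings, 642 and 659 with other filters, and 324 and 326 by limma on log2(FPKM + 1) and log2(FPKM + 0.1). Leaving out 1 library gave 379 to 592, with 390, 380 and 379 without si-hnrnpa2b1 replicate 1, 2 or 3; fewer libraries leave fewer degrees of freedom. Of the 650 genes, DESeq2 called 572 and limma on log2(FPKM + 1) called 304, all in the same direction. The number changed at least 2-fold was 24 by DESeq2, 6 and 17 by limma with the larger and smaller pseudocount, and 24 to 46 without 1 library, 24 being without si-hnrnpa2b1 replicate 2. A pseudocount of 1 shrinks the fold changes of low genes by construction; the cause of the other differences was not tested.

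Camera with an estimated correlation called 0 lists, 6 having an unadjusted p below 0.05, with adjusted p of 0.23 for lipogenesis, 0.17 for cholesterol synthesis, 0.21 for interferon and 0.16 for both ATF4 targets and endoplasmic reticulum chaperones. Leaving out 1 library left 9 to 12 lists called, and 9 of the 12 kept their call in each of these fits. Changed ATF4 targets numbered 12 by limma with either pseudocount and 12 to 21 without 1 library, with 13, 12 and 13 without si-hnrnpa2b1 replicate 1, 2 or 3. Endoplasmic reticulum chaperones numbered 3 to 9 without 1 library, with 3 without si-hnrnpa2b1 replicate 3, and lipogenesis genes 3 by limma with either pseudocount and 3 to 7 without 1 library, with 3 without NC replicate 1, si-hnrnpa2b1 replicate 1 or si-hnrnpa2b1 replicate 2. Interferon genes numbered 17 and sterol genes 12 by limma with either pseudocount, and 17 to 24 and 14 to 18 without 1 library. Apart from the smaller number of libraries, the cause was not tested.

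With the replicate number as a block, 481 genes changed, 28 of them at least 2-fold. Deviations from the group means of same-numbered libraries correlated at 0.057, -0.0039 and 0.059, none above 0.1. Of the 6 libraries, 4 correlated best with their own number. These values are a hint from the data and not from the design, and they cannot exclude that the numbers pair the libraries. At this depth edgeR recovered 46% of simulated changes of 0.3 on the log2 scale, so that changes of that size may have been missed. The simulation gave 169 calls against 650 in the fit reported, so this share need not hold for these data.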

Other observations

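The tests on leukocytes, on transfection or the siRNA itself, on reads shared between paralogs and on EGF family ligands were chosen only after the result was seen, as were the genes of the next paragraphs, and the medians without a length trend were added after the data were seen.

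Itga3, an integrin subunit that binds laminin, rose from 190 ± 8.72 to 305 ± 3.22 CPM (n = 3 per group, log2 0.69 ± 0.05, edgeR adjusted p = 5.2e-07), with the 3 si-hnrnpa2b1 libraries above the 3 NC libraries. Ccnd1, the cyclin that drives entry into the cell cycle, rose from 150 ± 6.82 to 222 ± 10.1 CPM (log2 0.56 ± 0.05, edgeR adjusted p = 8.8e-06). Il1rl1, which encodes the receptor of Il33, rose from 275 ± 8.65 to 392 ± 11.9 CPM (log2 0.51 ± 0.04, edgeR adjusted p = 7.1e-06). The transcripts of both ligand and receptor genes were thus higher, though counts per gene do not tell forms of a transcript apart. Cmpk2, a gene beside Rsad2 that interferon induces and that was on none of the lists, fell from 71.2 ± 8.43 to 36.3 ± 3.01 CPM (log2 -0.97 ± 0.09, edgeR adjusted p = 8.8e-06). These 4 calls kept their direction and their side of the threshold under all 15 alternatives.

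Some ligands of the EGF family rose, on no fixed list. Hbegf rose from 10.8 ± 1.16 to 17.7 ± 1.40 CPM (log2 0.71 ± 0.12, edgeR adjusted p = 0.0018) and Nrg1 by 0.96 on the log2 scale. Tgfa, near or below the 0.197 to 0.224 CPM that 3 counts represent in NC replicates 1 and 3 (0.141 and 0.269 CPM), went from 0.364 ± 0.282 to 1.57 ± 0.555 CPM (edgeR adjusted p = 0.019), a call lost without NC replicate 1, NC replicate 3, si-hnrnpa2b1 replicate 2 or si-hnrnpa2b1 replicate 3. Of the remaining EGF family ligands that were tested, Egf, Areg and Btc, 0 of 3 passed edgeR's test, with log2 fold changes of -0.63 ± 0.37, -0.11 ± 0.17 and 0.03 ± 0.26. As the ligands that passed had been set aside, this count does not test whether the family rises.

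Interferon genes lay lower in the si-hnrnpa2b1 libraries, 23 of 30 past the threshold. Leukocytes in the NC cultures are argued against, since their 13 markers, of which 7 had any count, summed to 2.22 ± 0.570 CPM in NC and 2.42 ± 0.746 CPM in si-hnrnpa2b1 libraries, led by Cd68 at 1.40 and 1.61 CPM, while Rsad2 and Cxcl10 together lost 237 CPM. A single NC library as the whole cause is argued against by the at least 19 genes that fell whichever NC library was left out. The trend of fold change on gene length ran only from -0.11 to 0.092 over all tested genes. Its removal left the list median at -0.46 but could not have taken the fall away, so the removal is no test. The small size of the trend alone argues against gene length as the whole cause. A response to transfection or to the siRNA itself, rather than to lowered Hnrnpa2b1, may account for the pattern only if it differed between the groups. As the genes lay lower after si-hnrnpa2b1, it would have to be a stronger rise in NC or a fall after si-hnrnpa2b1. Such a response cannot be told apart from an effect of lowered Hnrnpa2b1. The design holds 0 libraries outside the groups NC and si-hnrnpa2b1, and what the NC cells received is not given in the sources used here. A role of hnRNPA2B1 in the interferon response stays open as a hypothesis.

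Hnrnpa1 lay higher while its paralog Hnrnpa2b1 lay lower, and Hnrnpa3 less firmly so. Hnrnpa2b1 reads counted under its paralogs would pull both downward, whereas their log2 fold changes were 0.41 ± 0.04 and 0.18 ± 0.05. A second model named Hnrnpa3 gave 0.22 ± 0.06 and did not pass (edgeR adjusted p = 0.053). As the treatment of reads that map to several genes is not given, that model may hold the same reads and adds no separate support. Over 3 other scalings the lowest values were 0.41 for Hnrnpa1 and 0.18 for Hnrnpa3, but these moved the median of all genes by at most 0.0039, too little to be a test. Scaling moves all genes alike, and the median of all tested genes was -0.0015. That argues against scaling as the source of a rise relative to most other genes. Whether all transcripts changed together cannot be seen, since the scaling holds that median near 0. A response to lowered Hnrnpa2b1 and an effect of the siRNA by another route were not tested, and siRNA sequences were not used here.

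Most tested sterol genes lay lower and most tested ATF4 targets higher. A single library as the cause is argued against, since at least 14 sterol genes fell and at least 12 ATF4 targets rose whichever of the 6 libraries was left out, the latter down from 21 to 13, 12 and 13 without si-hnrnpa2b1 replicate 1, 2 or 3. Removing the trend on gene length left medians of -0.38 and 0.26, which is no test, since the trend ran only from -0.11 to 0.092. The small size of the trend alone argues against gene length as the whole cause. The partial fall of Hnrnpa2b1 mRNA, a response to transfection or to the siRNA itself, or a difference in growth or medium between the cultures could each underlie both changes. No value here separates them, and the data hold no protein values.

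The 6 libraries allow 10 splits into 3 and 3, the real split being 1 of them, too few for a share under 0.05. The real split gave 650 changed genes and the highest other 3; for genes changed at least 2-fold these were 39 and 3. For members changed they were 23 and 0 for interferon, 17 and 0 for sterol, 21 and 0 for ATF4 targets, and 9 and 0 for endoplasmic reticulum chaperones. Every other split puts NC and si-hnrnpa2b1 libraries on both sides, so a difference between the groups widens the spread within each side. Low counts of changed genes there are built in and give no chance level. Camera called 12 lists in the real split and 4 to 8 in each of the others. Those splits mix the groups unevenly, so their calls may hold part of the group difference and give no rate of false calls. How many of camera's 12 calls an arbitrary split would give thus cannot be told.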
